A study of Mus musculus with 9 samples.

How the data were processed

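RNA sequencing of pneumospheres, spheres that grow from dissociated mouse embryonic lung in suspension culture, was analysed at 3 times of culture, with 3 libraries each on day 3, day 7 and day 10. Per the labels' protocols, lungs of C57/B6 embryos were dissociated with trypsin and plated briefly on ordinary plastic, where mesenchymal cells attach. The cells left in the supernatant, described as enriched for epithelium, were grown in medium with basic FGF, EGF and heparin on low-attachment plates and were split on days 3 and 7. Poly(A) RNA was made into libraries with the Illumina TruSeq RNA kit. Sorted embryonic cells are mentioned in the extraction protocol and a genetic screen in the series title; neither was analysed here.

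The authors deposited 1 table of read counts per gene, with Entrez gene IDs, which are whole numbers without normalisation. The counts were made with featureCounts against the mouse build mm10, per the submitters' processing notes. The aligner, the gene annotation, the treatment of reads that map to several places and whether counting used strand are not given in the sources used here. Reads of overlapping and antisense genes therefore could not be told apart, and values of near-identical genes, such as the adult alpha globins Hba-a1 and Hba-a2 or the beta globins Hbb-b1 and Hbb-bs, depend on how shared reads were counted. The gene models of Col4a1 (chromosome 8, 11198423 to 11312889) and Col4a2 (11312805 to 11449287) overlap. All 9 columns matched 1 sample each by name. Of 27179 gene IDs, 25275 were named from the NCBI RefSeq annotation of the same mouse assembly and 18 from GENCODE release M21, and 1886 stayed unnamed. A single unnamed ID held 6.79% of the counts of day 3 replicate 2 and between 0.169% and 0.515% of those of the other 8 libraries.

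Library totals ran from 20716878 to 30466712 counts. A count of 0 allows up to 3 counts in a library, which is 0.0985 to 0.145 CPM (counts scaled by the library total). This floor and all counting intervals cover counting error only, since reads without molecular identifiers are not independent molecules. No label says that the 3 libraries of a day came from separate cultures or litters. The p-values then measure the spread between these samples. Sex-linked transcripts differ between replicates of a day, so this spread is not purely technical. Replicates of a day were compared by a chi-square test on their counts. The statistic per degree of freedom lay between 8.50 and 135, so no pair differed by as little as counting noise alone.

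Gene tests used edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr (14940 of 27179), scaled by TMM factors and fitted with the robust quasi-likelihood model over all 9 libraries, which share 1 estimate of the spread (biological coefficient of variation 0.146). Each pair of days was compared with the quasi-likelihood F test, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The same model tested whether a gene differed among the 3 days and whether its second step (day 10 minus day 7) differed from its first (day 7 minus day 3). These steps span 3 and 4 days, so day 7 also came longer after a split than day 10. Levels are TMM-normalised CPM, given as mean ± SD with n = 3 libraries per day. Fold changes are log2, and their standard error is the absolute log2 change divided by the square root of F. For a gene with no count on a day, the fold is a bound computed with 3 counts per library. For a gene with 1 to 3 counts on a day, it is a ratio with its 95% counting interval.

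Gene lists were tested with camera from limma 3.58.1 (preset correlation 0.01) on log2 CPM with a prior count of 2. The adjusted p covers 28 lists in 3 comparisons, 84 tests. The 30 lists were distal tip progenitor, general lung epithelium, proximal airway and basal cell, secretory cell, ciliated cell, neuroendocrine cell, alveolar type 2 cell, alveolar type 1 cell, mesenchyme, smooth muscle, mesothelium, endothelium, leukocyte, erythroid cell, neural crest with neuron and glia, other endoderm, chromosomal passenger and mitosis, DNA replication, FGF and ERK target, Wnt target, Hedgehog target, Notch target, BMP and TGF-beta target, YAP target, hypoxia response, cholesterol synthesis, p53 and cell cycle arrest, unfolded protein and amino acid stress, interferon response, and matrix and basement membrane. Secretory cell and other endoderm had 1 tested member each and no list test. Several genes are in more than 1 list (Spry2, Etv4, Etv5, Id2, Ccn2, Foxf1, Muc16 and Sesn2). Camera assumes that members are nearly uncorrelated, and the adjusted p with an estimated correlation is given beside that of each called list.

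The groups, tests, lists and the rule for named genes were chosen before the data were examined. The rule always names Sox9, Nkx2-1, Epcam, Aurkb and Vim. For each comparison it adds the 8 largest rises and the 8 largest falls among called genes with a mean of at least 10 CPM in the higher group and no overlap between replicates, leaving out predicted loci, clones and pseudogenes. From each list it adds up to 4 members with the smallest p, and any member needed to state a count of 5 or fewer. Some members that the rule names are not reported here.

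The gene test was checked on simulated counts with the real means and library sizes. Of 100 genes changed 2-fold it recovered 71 for day 7 against day 3, 70 for day 10 against day 7 and 68 for day 10 against day 3. Of 100 genes changed 4-fold it recovered 90, 93 and 94, with 10, 9 and 9 false calls among 14751, 14775 and 14754 genes. No other gene was changed there, whereas the real comparisons called 41.8%, 8.51% and 56.7% of genes. The recovered shares and false calls need therefore not hold for the real comparisons. In 2 of 20 simulations with no change camera called a list. Simulated genes were drawn independently, while the correlation estimated in the real mitosis list was 0.966. The simulations therefore cannot give the rate of false list calls in the real data.

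Alternatives were DESeq2 1.42.0, limma-voom, DESeq2 size factors, upper-quartile factors or library size alone in edgeR, no filter, a filter of 1 CPM in 3 libraries, a fit to only the groups compared, a test against a log2 change of 1, the replicate number as a block, camera with an estimated correlation, camera with a prior count of 0.5, fry, and leaving out each library in turn. After the data were seen, fits without the unnamed ID and without both day 3 replicate 2 and day 10 replicate 3, and camera with both the block and an estimated correlation, were added. Tables and figures were made with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9.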

Results

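The series followed cells of the embryonic mouse lung through serial passage as pneumospheres, to see which transcripts change during culture. Its title concerns Aurora kinase B, the mitotic kinase encoded by Aurkb, and progenitors that carry the transcription factor Sox9. Poly(A) RNA was sequenced from 3 libraries on each of days 3, 7 and 10. Counts summed to between 20716878 and 30466712 per library. On log2 CPM, libraries of 1 day correlated across genes at r = 0.979 to 0.993, libraries of days 3 and 7 at 0.938 to 0.945, and libraries of days 3 and 10 at 0.898 to 0.918. Genes are not independent replicates, so these values only describe the libraries. The first principal component held 73.7% of the variance and separated day 3 from the later days.

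Transcripts of lung epithelium were scarce on every day. Nkx2-1, the transcription factor that specifies lung endoderm (Entrez 21869, chromosome 12, 56531935 to 56536908), had 0 counts in all 9 libraries, as had Foxa1 and Shh, which allows at most 0.145 CPM in any of them. Epcam, an epithelial adhesion molecule (Entrez 17075, chromosome 17, 87635979 to 87651127), stood at 0.599 ± 0.207 CPM on day 3, 0.117 ± 0.1 on day 7 and 0.113 ± 0.0396 on day 10. Without Gata6 and Fgfr2, which mesenchymal cells also express, the other 16 genes of the general lung epithelium list together had 32 to 78 counts per library, or 1.34 to 2.96 CPM. Gata6 stood at 49.0 ± 6.54, 43.1 ± 8.63 and 34.7 ± 10.1 CPM on the 3 days. Mesenchymal transcripts were abundant in the same libraries. Vim, an intermediate filament of mesenchymal cells (Entrez 22352, chromosome 2, 13574311 to 13582826), stood at 661 ± 43.4 CPM on day 3, and Col1a1, a chain of type I collagen, at 3858 ± 259 CPM.

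Between day 3 and day 10, Sox9 (Entrez 20682, chromosome 11, 112782210 to 112787757) rose from 51.3 ± 4.72 to 85.0 ± 26.5 CPM, a log2 change of 0.73 (SE 0.20, adjusted p = 0.0119). These data do not show which cells carried Sox9. With epithelial transcripts so scarce, its rise cannot be read as one of epithelial progenitors. Aurkb (Entrez 20877, chromosome 11, 69045624 to 69051664) fell from 90.1 ± 2.80 to 33.6 ± 13.3 CPM, a log2 change of -1.43 (SE 0.26, adjusted p = 0.00125). Epcam fell by 2.39 on the log2 scale (SE 0.57, adjusted p = 0.00486), and Vim rose by 0.30 (SE 0.12, adjusted p = 0.0478). The rises included genes of extracellular matrix. Lamc3, a laminin chain, went from 0.598 ± 0.237 to 135 ± 11.2 CPM (log2 change 7.82, SE 0.34), and Col5a3, a chain of type V collagen, from 3.69 ± 0.742 to 692 ± 170 CPM (7.55, SE 0.24). Comp, a cartilage and tendon matrix protein, reached 21.5 ± 18.2 CPM from 0.168 ± 0.111. Adh1, an alcohol dehydrogenase, reached 52.0 ± 25.7 CPM from 0.335 ± 0.131, and the transporter gene Abca8a reached 350 ± 117 CPM from 2.52 ± 0.766. S100a4, a calcium-binding protein of fibroblasts, Crabp1, which binds retinoic acid, and Sema7a, a membrane-anchored semaphorin, rose by 7.24, 6.92 and 6.76 on the log2 scale.

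The falls from day 3 to day 10 included globins and other red cell genes. Hbb-y, an embryonic beta globin, went from 935 ± 90.4 to 0.123 ± 0.0681 CPM (log2 change -12.84, SE 0.29) and Hba-x, an embryonic alpha globin, from 107 ± 7.01 to 0.0652 ± 0.0356 CPM (-10.51, SE 0.24). Hba-a2 fell from 78.7 ± 8.31 to 0.106 ± 0.0999 CPM. Slc4a1, the red cell anion exchanger, had 16.6 ± 4.21 CPM on day 3 and no count on day 10, at least 133-fold lower, and the beta globin Hbb-b1 was at least 125-fold lower. Mpzl2, an adhesion molecule of epithelial and blood cells, fell from 16.7 ± 0.696 to 0.0833 ± 0.0146 CPM. Cartpt, a neuropeptide precursor, and Lhx3, a homeobox factor of motor neurons and pituitary, fell from 17.5 ± 7.94 and 14.6 ± 2.25 CPM to 0.0534 and 0.0471 CPM, and their day 10 counts came from a single library each. All 7 tested genes of the erythroid cell list fell (camera adjusted p = 1.18e-06; adjusted p = 0.2 with an estimated correlation). Their median log2 change was -10.1, and -8.76 with the 2 members that had no count on day 10 at their bounds. Summed erythroid counts went from between 1047 and 1254 CPM to between 0.424 and 1.08 CPM.

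Lists of neural and endocrine cells and of mesothelium also fell. In the neural crest, neuron and glia list, 8 of 10 tested genes fell (median -5.53; adjusted p = 0.000681, and adjusted p = 0.378 with an estimated correlation). Ret, a receptor tyrosine kinase of enteric and other neurons, fell from 59.0 ± 8.98 to 1.66 ± 0.953 CPM, and the neuronal RNA-binding protein gene Elavl4 from 14.5 ± 2.45 to 0.257 ± 0.0898 CPM. The neuroendocrine cell list had 6 of 7 tested genes lower (median -2.61; adjusted p = 0.00171, and adjusted p = 0.277 with an estimated correlation). They included Uchl1, a neuronal deubiquitinase (22 ± 2.51 to 3.63 ± 0.968 CPM). Chga stood at 1.62 ± 0.529 and 1.65 ± 0.655 CPM. The 3 tested mesothelium genes Lrrn4, Wt1 and Aldh1a2 changed by -5.73, -1.68 and -1.62 on the log2 scale (adjusted p = 0.0189 for the list, and adjusted p = 0.277 with an estimated correlation).

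Genes of cell division and sterol synthesis fell over the same days as these cell type markers. All 18 genes of the chromosomal passenger and mitosis list fell (median -1.55; adjusted p = 1.5e-05, and adjusted p = 0.563 with an estimated correlation). Bub1b, a spindle checkpoint kinase, went from 171 ± 2.35 to 54.4 ± 16.6 CPM, Plk1, a mitotic kinase, from 101 ± 3.73 to 32.9 ± 13.6 CPM, and Cdc20, an activator of the anaphase-promoting complex, from 113 ± 4.86 to 38.7 ± 15.1 CPM. All 15 genes of the DNA replication list fell (median -1.06; adjusted p = 1.5e-05, and adjusted p = 0.536 with an estimated correlation). Mcm7, a subunit of the replicative helicase, went from 159 ± 2.65 to 70.8 ± 7.87 CPM. Of the day 10 libraries, replicate 3 stood apart: the median log2 difference of these 33 genes from the day 3 mean was -2.28 there and -1.07 and -1.11 in replicates 1 and 2. Left out, that library left all 18 and all 15 genes lower. All 16 genes of the cholesterol synthesis list fell (median -0.96; adjusted p = 6.3e-05, and adjusted p = 0.563 with an estimated correlation). They included Srebf2, the transcriptional activator of the pathway (503 ± 20.9 to 300 ± 15.0 CPM).

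Genes of mesenchyme, basement membrane and growth arrest rose on balance. In the mesenchyme list 14 of 19 genes rose and 3 fell (median 0.95; adjusted p = 0.00171, and adjusted p = 0.277 with an estimated correlation). Prrx1, a homeobox factor of limb and craniofacial mesenchyme, went from 4.40 ± 0.886 to 177 ± 30.4 CPM (log2 change 5.32, SE 0.17), and Dcn, the proteoglycan decorin, from 367 ± 9.32 to 2476 ± 319 CPM. The members that fell were Tbx4, Tbx5 and Tcf21, transcription factors of lung mesenchyme, with log2 changes of -2.73 (SE 0.22), -2.81 (SE 0.11) and -1.40 (SE 0.24). In the matrix and basement membrane list 8 of 14 tested genes rose (median 0.96; adjusted p = 0.0138, and adjusted p = 0.277 with an estimated correlation). Col4a1 and Col4a2, the main chains of type IV collagen, reached 9127 ± 146 and 5382 ± 32.2 CPM from 1335 ± 42.2 and 874 ± 15.4 CPM. Fbln1, which encodes fibulin-1, fell by 1.82 (SE 0.29). In the p53 and cell cycle arrest list 11 of 12 genes rose and none fell (median 0.90; adjusted p = 0.000801, and adjusted p = 0.536 with an estimated correlation). Cdkn1a, which encodes the inhibitor p21, reached 95.1 ± 44.4 CPM from 14.2 ± 1.70, and Cdkn2b, another inhibitor of cyclin-dependent kinases, 18.1 ± 8.16 CPM from 1.04 ± 0.319.

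**Figure D1:**
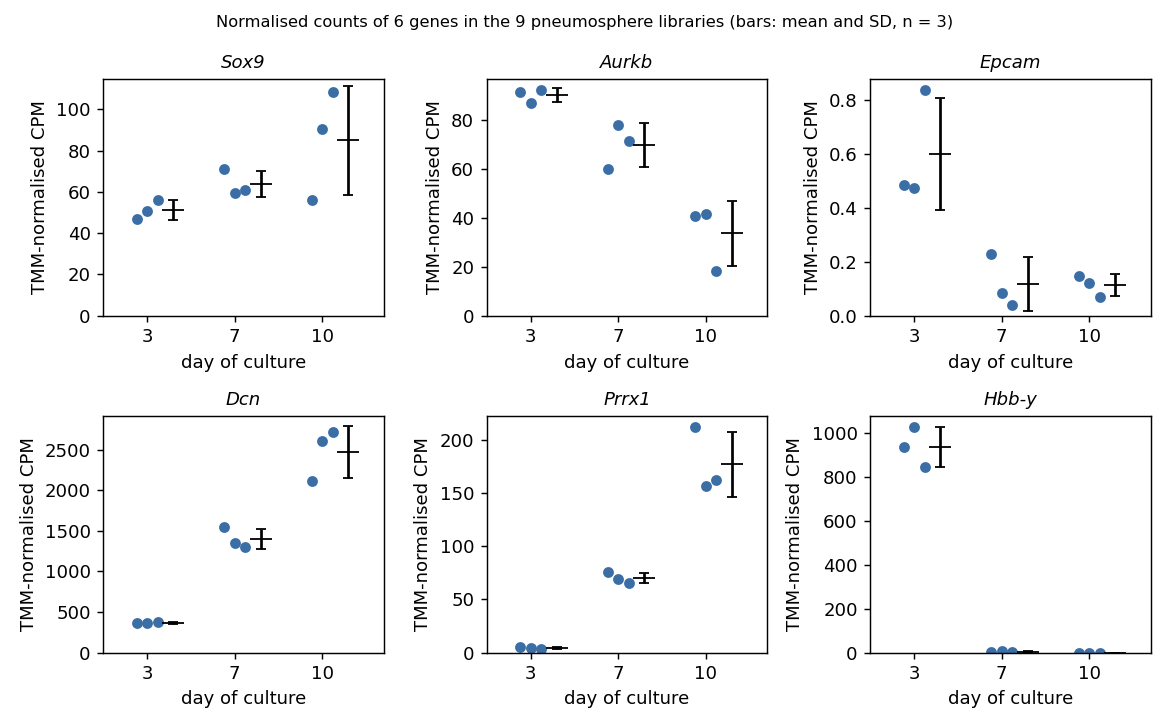
Normalised counts (TMM-normalised CPM, vertical axes) of Sox9, Aurkb, Epcam, Dcn, Prrx1 and Hbb-y by day of culture (horizontal axes), with 1 point per library and the mean and SD of the 3 libraries of each day beside them. Sox9 and Aurkb spread most on day 10, where Aurkb is lowest in replicate 3 (18.2 CPM), and Epcam stays under 1 CPM in every library.

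The other lists did not pass for day 10 against day 3. In the distal tip progenitor list, which holds Sox9, 2 of 12 tested genes rose and 5 fell (adjusted p = 0.169). Besides Sox9, Clu, which encodes clusterin, rose from 3.22 ± 0.636 to 22.2 ± 6.50 CPM. The falls were in Mycn (24.3 ± 6.38 to 4.89 ± 1.80 CPM), Hmga2 (105 ± 17.0 to 8.92 ± 6.56 CPM), Bex1, Id2, and Lin28b, which had no count on day 10 and was at least 18.3-fold lower. In the general lung epithelium list (5 of 18 genes tested, adjusted p = 0.705) Epcam and Fgfr2 fell, the latter from 20.2 ± 0.827 to 5.24 ± 1.66 CPM, and Cldn7 and Elf3 rose to 1.16 ± 0.374 and 0.502 ± 0.136 CPM. Proximal airway and basal cell (adjusted p = 0.757), ciliated cell (0.960), alveolar type 2 cell (0.885) and alveolar type 1 cell (0.805) had members going both ways. The single tested members of the secretory cell and other endoderm lists, Foxa3 and Lgals4, rose to 1.03 ± 0.512 and 12.1 ± 2.03 CPM. Smooth muscle (0.0751) had 5 of 7 tested genes higher, led by the actin-binding Tagln (10.8 ± 1.58 to 173 ± 69.6 CPM), endothelium (0.169, and 0.0312 with the replicate number as a block, where adjusted p = 0.344 with an estimated correlation) had Erg, Tek and Kdr lower, and leukocyte (0.348) had Laptm5 lower. The signalling lists gave adjusted p of 0.805 for FGF and ERK target, 0.926 for Wnt target, 0.780 for Hedgehog target, 0.376 for Notch target, 0.0593 for BMP and TGF-beta target and 0.0591 for YAP target. The stress lists gave 0.604 for hypoxia response, 0.0633 for unfolded protein and amino acid stress and 0.174 for interferon response.

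Across all genes, edgeR called 8473 of 14940 between day 3 and day 10, of which 4408 were higher and 4065 lower on day 10 (52% higher). The balance turned with library size alone (3639 higher and 4722 lower, 43.5% higher) and with upper-quartile factors (4199 and 4334). Of the 8473 genes called in the main fit, 1892 rose and 1359 fell by at least 2-fold. Adjusted over the list alone, the counts of members that rose and fell were equal to those over all genes in every list but general lung epithelium (3 fell), BMP and TGF-beta target (8 rose against 6) and hypoxia response (1 rose and 2 fell against 2 and 3). The call of Vim ended in 6 of 9 fits without a single library, with an adjusted p of up to 0.151 (without day 3 replicate 2). It also ended with DESeq2 size factors, upper-quartile factors, library size alone (0.192), the filter of 1 CPM in 3 libraries, the replicate block (0.0664) and without both day 3 replicate 2 and day 10 replicate 3 (range over alternatives 0.0262 to 0.192). That of Sox9 ended only without those 2 libraries (0.0857, range 0.00015 to 0.0857). The call of Id2 ended in 4 fits without a single library (up to 0.106, without day 10 replicate 3, range 0.00306 to 0.181), and that of Kdr without day 10 replicate 3 (0.0630, range 0.000286 to 0.105). Without day 10 replicate 1 the log2 changes of S100a4, Comp, Crabp1 and Sema7a were 5.82, 6.01, 5.85 and 6.00, and that of Hmga2 was -4.29. Without day 10 replicate 3 the median of the mitosis list was -1.25, and without day 3 replicate 2 Elf3 had no count on day 3.

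**Figure D2:**
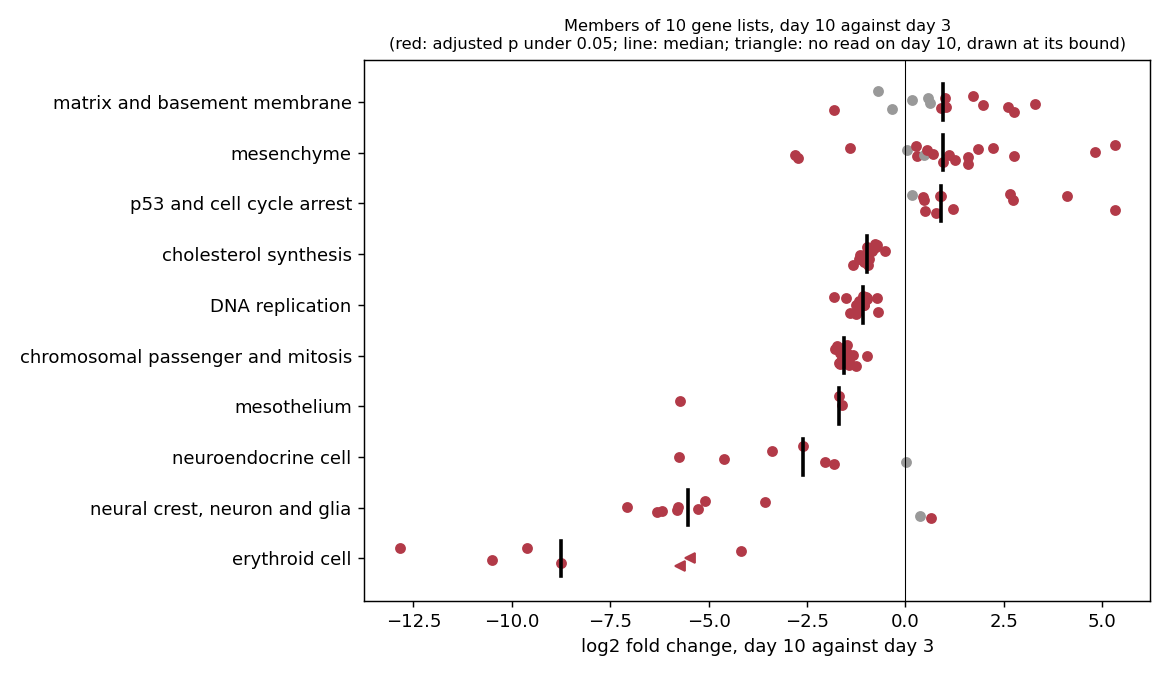
Log2 fold change from day 3 to day 10 (horizontal axis) of each tested member of the 10 gene lists that camera called (vertical axis), in red where the gene's adjusted p was under 0.05, with black lines at the medians and triangles for genes without a count on day 10, drawn at their bound. All members of the cholesterol synthesis, DNA replication and mitosis lists lie left of 0, and the mesenchyme list has 3 red members left of 0 (Tbx4, Tbx5 and Tcf21).

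The first step, from day 3 to day 7, already held many of these changes. The rises included Comp, from 0.168 ± 0.111 to 20.3 ± 11.8 CPM (log2 change 6.90, SE 0.95) and Lamc3 to 47.9 ± 15.6 CPM (6.33, SE 0.33). Others were Fst, the activin antagonist follistatin, from 0.406 ± 0.161 to 28.4 ± 13.4 CPM (6.09, SE 0.47), Timp4, a metalloproteinase inhibitor, to 31.1 ± 6.56 CPM, and Spp1, which encodes osteopontin, from 2.46 ± 1.33 to 128 ± 32.5 CPM. Sema7a, Adh1 and Abca8a rose by 6.20, 6.18 and 5.41. Hbb-y, Hba-x and Hba-a2 changed by -7.85 (SE 0.21), -7.25 (SE 0.18) and -7.13 (SE 0.29), to 4.08 ± 1.13, 0.698 ± 0.249 and 0.552 ± 0.235 CPM. Slc4a1 kept 1 count on day 7, a level lower by a ratio of 1320 (95% counting interval 236 to 52200), and Hbb-b1 kept 2 counts (622, 172 to 5140). Mpzl2 and Nap1l2, a nucleosome assembly gene of neurons, changed by -6.37 and -5.03, and Lhx3 fell to 0.289 CPM. Sox9 stood at 63.8 ± 6.49 CPM on day 7 (log2 change 0.32, adjusted p = 0.239), Aurkb at 69.6 ± 9.10 CPM (-0.37, adjusted p = 0.268) and Vim at 723 ± 94.0 CPM (0.13, adjusted p = 0.408). Epcam fell by 2.23 (SE 0.54, adjusted p = 0.00842).

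Of the 28 lists, camera called 12 for day 7 against day 3, 5 higher and 7 lower (0 with an estimated correlation; fry called 17). All 7 tested members fell in the erythroid cell list (adjusted p = 2.07e-08, and adjusted p = 0.2 with an estimated correlation). Its median was -7.25, or -7.13 with Hba-a1 at its bound. All 7 also fell in the neuroendocrine cell list (adjusted p = 0.000119, and adjusted p = 0.26 with an estimated correlation). In the neural crest, neuron and glia list 8 of 10 fell, such as Ret (to 4.45 ± 0.362 CPM; list adjusted p = 0.000169, and adjusted p = 0.324 with an estimated correlation). All 3 mesothelium genes fell (adjusted p = 0.0168, and adjusted p = 0.277 with an estimated correlation). Cholesterol synthesis had 12 of 16 genes lower (adjusted p = 0.000251, and adjusted p = 0.593 with an estimated correlation) and DNA replication 6 of 15 (adjusted p = 0.0039, and adjusted p = 0.637 with an estimated correlation). In the mitosis list Bub1b, Ccnb1, Cdc20, Cenpe and Aurka fell, 5 of 18 genes (adjusted p = 0.00798, and adjusted p = 0.714 with an estimated correlation). The lists that rose were mesenchyme (12 rose and 3 fell of 19; adjusted p = 0.00403, and adjusted p = 0.277 with an estimated correlation) and matrix and basement membrane (6 rose and Fbln1 fell of 14; adjusted p = 0.0109, and adjusted p = 0.277 with an estimated correlation). The p53 and cell cycle arrest list rose as well (8 of 12 rose; adjusted p = 0.000768, and adjusted p = 0.536 with an estimated correlation). BMP and TGF-beta target had 8 of 11 genes higher (adjusted p = 0.000768, and adjusted p = 0.277 with an estimated correlation), among them the inhibitory Smad6 (13.3 ± 0.132 to 32.0 ± 6.14 CPM). YAP target had 6 of 8 higher and Ajuba lower (adjusted p = 0.0114, and adjusted p = 0.277 with an estimated correlation), with Ccn2, a matricellular growth factor in both lists, at 45.0 ± 6.43 CPM from 1.09 ± 0.205.

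In this step edgeR called 6240 genes, 3399 higher and 2841 lower on day 7 (2946 and 3004 with library size alone, 3067 and 3311 with upper-quartile factors), with 1341 rises and 790 falls of at least 2-fold. Adjusted over the list alone, no mitosis gene passed, 8 DNA replication and 9 p53 genes did, 7 matrix genes rose and 1 fell, and the other lists named in this step gave equal counts. Members called lower in the mitosis list were 1 in each of the 6 fits without a day 3 or day 7 library, 3 without day 10 replicate 2 and 17 without day 10 replicate 3. In the DNA replication list they were 5 to 11, the latter without day 10 replicate 3. Fbln1 was not called without day 7 replicate 1 or replicate 3. Aurkb, not called in the main fit, was called lower without day 10 replicate 3 (log2 change -0.37, adjusted p = 0.00678). It was also called without both day 3 replicate 2 and day 10 replicate 3, and in the fit to only the 2 groups compared. Sox9 was called higher without day 10 replicate 1 (0.32, adjusted p = 0.0366) and in that 2-group fit. Without day 7 replicate 1 the changes of Mpzl2 and Epcam were -7.31 and -3.20, and the adjusted p of Aurka, Cenpe and Ccnb1 rose to 0.137, 0.134 and 0.0977. The replicate block ended the calls of Aurka and Cenpe.

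The second step, from day 7 to day 10, held fewer called genes. Col5a3 rose from 137 ± 13.4 to 692 ± 170 CPM (log2 change 2.34, SE 0.18, adjusted p = 0.000763) and Lum, the matrix proteoglycan lumican, from 178 ± 26.0 to 776 ± 203 CPM (2.13, SE 0.20, adjusted p = 0.00151). Mmp19, a matrix metalloproteinase, rose from 10.7 ± 1.89 to 48.3 ± 9.92 CPM (2.17, SE 0.20, adjusted p = 0.00146). Cp, which encodes the copper carrier ceruloplasmin, Nptx2, a neuronal pentraxin, and Agt, the angiotensin precursor, rose by 3.19 (SE 0.50), 2.25 (SE 0.34) and 2.22 (SE 0.33), and Crabp1 and Cpz, a secreted carboxypeptidase, by 2.43 and 2.37. The falls included Prph, a neuronal intermediate filament (10.9 ± 7.64 to 1.18 ± 0.674 CPM), Kdr, a VEGF receptor of endothelial cells (91.8 ± 52.2 to 12.8 ± 10.2 CPM), and Aqp1, a water channel (43.5 ± 20.6 to 6.32 ± 2.02 CPM). The matrix genes Ltbp2 and Thbs4, the tendon transcription factor gene Scx, the imprinted gene Nnat and Tmem150c changed by -2.32, -2.07, -2.18, -2.35 and -1.86. Aurkb fell by 1.06 (SE 0.26, adjusted p = 0.0380). Sox9 differed by 0.42 (adjusted p = 0.236), Vim by 0.18 (adjusted p = 0.398) and Epcam by -0.16 (adjusted p = 0.919).

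Camera called 13 lists in this step, 4 higher and 9 lower (0 with an estimated correlation; fry called 10). In the DNA replication list 10 of 15 genes fell, such as Mcm7 (fell by 0.51, SE 0.09) and Mcm6 (fell by 0.57, SE 0.11; list adjusted p = 1.49e-08, and adjusted p = 0.425 with an estimated correlation). The mitosis list had a median of -0.93 (adjusted p = 1.6e-08, and adjusted p = 0.536 with an estimated correlation), but only Bub1b, Aurkb and Cdk1 passed singly, 3 of 18. Cholesterol synthesis had Srebf2 alone of 16 lower (adjusted p = 0.000928, and adjusted p = 0.634 with an estimated correlation). No gene of 14 passed with edgeR in hypoxia response (median -0.49; adjusted p = 0.00411, and adjusted p = 0.634 with an estimated correlation). Cell type lists that fell were erythroid cell, with Hbb-y, Hba-x and Hba-a2 lower (adjusted p = 0.00171, and adjusted p = 0.277 with an estimated correlation), and neural crest, neuron and glia, with Elavl4, Stmn2 and Ret among the genes lower (adjusted p = 0.00113, and adjusted p = 0.406 with an estimated correlation). The endothelium list fell too, with Emcn and Kdr lower and the other 8 genes not called (adjusted p = 0.0119, and adjusted p = 0.563 with an estimated correlation). In day 7 replicate 1 Emcn and Kdr had 169 and 70.3 CPM, while Pecam1 and Cldn5 of the same list had 0.296 and 0.132 CPM. The fall of Emcn and Kdr need therefore not be one of endothelial cells. In the distal tip progenitor list Id2 and Mycn fell and Clu rose (adjusted p = 0.0278, and adjusted p = 0.277 with an estimated correlation). In BMP and TGF-beta target Id1, Id2, Skil and Smad7 fell (adjusted p = 0.0332, and adjusted p = 0.536 with an estimated correlation). Mesenchyme had 7 of 19 genes higher, and Tbx4 and Tbx5 lower (adjusted p = 0.0011, and adjusted p = 0.277 with an estimated correlation). Matrix and basement membrane had Col4a1, Col4a2, Sparc and Nid1 higher (adjusted p = 0.0128, and adjusted p = 0.277 with an estimated correlation). Ddit3, Trib3 and Herpud1 rose in the unfolded protein and amino acid stress list (adjusted p = 0.0136, and adjusted p = 0.634 with an estimated correlation). Ifitm3 was among the genes that rose in interferon response (adjusted p = 0.0297, and adjusted p = 0.536 with an estimated correlation).

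Between day 7 and day 10 edgeR called 1271 genes, 659 higher and 612 lower (51.8% higher; 437 higher and 675 lower, 39.3% higher, with library size alone; 38.3% with limma-voom), with 193 rises and 223 falls of at least 2-fold. Adjusted over the list alone, all 18 mitosis and all 15 DNA replication genes passed, 6 neural genes fell, and 5 BMP and TGF-beta target, 5 distal tip, 5 matrix, 4 unfolded protein and 4 interferon genes passed in the direction of the list. Without day 7 replicate 2, 304 genes were called, with 1 DNA replication gene, no mitosis, BMP or cholesterol gene, and no fall in the distal tip list. Without day 3 replicate 1, day 3 replicate 2, day 7 replicate 1 and day 7 replicate 3, 780, 807, 829 and 667 genes were called, and mitosis genes numbered 0, 0, 2 and 0. In each of the 3 fits without a day 7 library 2 neural genes and 1 unfolded protein gene passed, and Srebf2 was called in 2 of the 9 fits without a single library. The adjusted p of Aurkb, Crabp1, Cpz, Prph, Nnat, Scx and Thbs4 rose to 0.138, 0.164, 0.117, 0.0750, 0.148, 0.0938 and 0.0532 without it, and that of Kdr was 0.0704, 0.0646 and 0.0858 without day 7 replicate 2, day 10 replicate 1 and day 10 replicate 3. Over all alternatives the adjusted p of Aurkb ranged from 0.000693 to 0.138 and that of Kdr from 0.000204 to 0.102. Sox9, not called in the main fit, was called higher without day 10 replicate 1 (log2 change 0.64, adjusted p = 0.0174). Its log2 change ran from 0.20 to 0.64 over the fits without a single library. The call of Hba-a2 ended in 6 of 9 fits without a single library (up to 0.105, without day 7 replicate 3, range over alternatives 0.00065 to 0.105) and with the replicate block. That block also ended the calls of Crabp1, Nnat, Ret and Cdk1. Those of Bub1b, Cdk1, Mcm6, Id1, Id2, Mycn, Skil, Smad7, Ret, Tbx4, Nid1, Trib3, Herpud1 and Ifitm3 each ended in at least 1 fit without a single library. Without day 10 replicate 3 the mitosis list had 16 genes lower (median -0.62) and hypoxia response 5, and Cp and Cpz rose by 2.51 and 1.60. With limma-voom Cp, Crabp1, Cpz, Nptx2, Agt and Prph were not called (adjusted p = 0.164, 0.525, 0.140, 0.0522, 0.245 and 0.0506). Without day 10 replicate 1 Crabp1 rose by 1.36 and cholesterol synthesis had 6 genes lower.

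The steps were also compared with each other. Tests among the 3 days together called 7988 genes. The second step differed from the first for 1199 genes, with a lower value in the second step for 891 and a higher one for 308. Ltbp2, which encodes a latent TGF-beta binding protein, rose from 0.799 ± 0.1 to 20.2 ± 4.68 CPM and then fell to 4.07 ± 1.12 CPM, and Aqp1 went from 5.76 ± 0.761 through 43.5 ± 20.6 to 6.32 ± 2.02 CPM. For Aurkb and Sox9 the steps were not called different (adjusted p = 0.413 and 0.909). Without single libraries the count ran from 552, without day 7 replicate 1, to 1817, without day 10 replicate 3.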

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

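Of the tests in this part, those of reads in the annotation and of the day 10 cycling genes without replicate 3 were chosen only after the result was seen.

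Some genes turned back between the steps. In the test of the second step against the first, 76 genes that had risen from day 3 to day 7 fell from day 7 to day 10, and 23 that had fallen rose, each called in both steps. Among those with higher levels, the second step minus the first was -6.97 on the log2 scale for Ltbp2 (0.799 ± 0.1, 20.2 ± 4.68 and 4.07 ± 1.12 CPM on days 3, 7 and 10), -5.71 for Aqp1, -4.39 for Pcsk6, a proprotein convertase, and -4.26 for Lhx2, a homeobox factor. It was 1.22 for Tmcc3, 1.26 for Tnik, 1.33 for Plxnc1, a semaphorin receptor, and 2.16 for Gfra1, the GDNF co-receptor (47.8, 25 and 59.0 CPM). By the labelled days, day 7 came 4 days after a split, and day 10 came 3 days after one. A turn on day 7 therefore cannot be told apart from an effect of this interval.

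These calls were set against other splits of the 9 libraries into 3 groups of 3, 100 of 280 being drawn. For genes that differ among the 3 days, 1 of 100 splits, the real one, gave as many as 7988 genes, and the highest of the others gave 6837. The real grouping thus gave the most genes of the splits drawn. That makes chance an unlikely account of the count but does not exclude it. For the difference between steps, 5 of 100 splits gave as many as 1199 genes, and the highest gave 7663, so these splits do not exclude chance. They do not speak for it either, because the other 4, with 2844, 4943, 7599 and 7663 genes, all keep the day 3 libraries together and so carry the difference of day 3. They either put all day 3 libraries in the middle or kept day 3 first and mixed days 7 and 10, which points to the structure of the samples, with day 3 far from the later days. In simulated counts with no change, edgeR called 1 gene for the difference between steps. Genes were drawn independently there, with the fitted spread equal on all days, so this cannot show that the real calls exceed chance.

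With 3 libraries against 3, the 10 splits are too few for a share under 0.05. The real split was 1 of 10 each time, with 6240 genes against 0 in the highest of the others for day 7 against day 3, 1271 against 0 for day 10 against day 7, and 8473 against 0 for day 10 against day 3. For lists the real and highest other counts were 12 and 10, 13 and 10, and 10 and 7.

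Reads from lung epithelial genes were few in cultures that the labels describe as enriched for epithelium. Loss of the whole set from the annotation or the counting is argued against, since 15 of the 18 genes had a read in some library. Some of them had few, such as Cldn3 with 2 reads in all. For Nkx2-1, Foxa1 and Shh, which had no read, this test cannot tell a loss in the counting from absence. A candidate explanation is that epithelial cells make up little of these cultures. A second list of 24 epithelial genes, written before its values were seen, had a median of at most 0.101 CPM in any library, and 18 of its genes stayed under 1 CPM everywhere, which is consistent with that explanation. A swap with samples of another origin was not tested, and no biological cause of a loss was.

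Mitosis and DNA replication genes were lower on day 10 than on day 3, with a median log2 change of -1.42 over 33 genes. Collagen genes rose from between 2.49% and 2.7% of all counts to between 8.44% and 8.60%. Shares this small leave little room to shift other genes, so a refit without them could hardly have come out otherwise. The counts they took up do not account for the fall: without them, scaled by library size alone, the median was -1.42. Nor does the single library day 10 replicate 3, since without it the median was -1.13. A slower cell cycle and a change in cell types stay open as untested. By the labelled days, day 3 came 3 days into culture and day 10 came 3 days after the split on day 7. These equal intervals argue against a longer time since plating or splitting as the account of this fall. Whether plating and splitting act alike was not tested.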

How the results depend on the processing

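The fits without the unnamed gene ID, without both day 3 replicate 2 and day 10 replicate 3, and with both the block and an estimated correlation were chosen only after the data were seen. No list passed with an estimated correlation (0, 0 and 0 for day 7 against day 3, day 10 against day 7 and day 10 against day 3), and fry called 21 for day 10 against day 3. DESeq2 called 2114 genes for day 10 against day 7. A fit to only the 2 groups compared called 290 there, against 1271 in the main fit. That fit called 7378 against 6240 for day 7 against day 3 and 8017 against 8473 for day 10 against day 3. Fewer samples thus did not lower the count in each comparison. Without a single day 3 library, 780, 807 and 876 genes were called for day 10 against day 7. The count of this step therefore depends on libraries outside the comparison. Tested against a log2 change of 1, a stricter question, 936, 2 and 1821 genes passed. Without single libraries the counts ran from 4778 to 7150, from 304 to 1548 and from 7328 to 8452 genes, from 6408 to 8237 among the 3 days, from 552 to 1817 for the step difference, and from 12 to 12, from 9 to 13 and from 10 to 13 lists. Where 1 library of a day pair was left out, the fit pools the spread of the others. Causes of these differences were not tested. Filters, scalings and the unnamed gene ID moved no total of called genes by 1.5-fold, but genes higher on day 10 than on day 7 went from 659 to 437 with library size alone.

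For day 10 against day 7, counts fell to 780, 807, 829, 304 and 667 without day 3 replicate 1, day 3 replicate 2, day 7 replicate 1, day 7 replicate 2 and day 7 replicate 3. The log2 change of Epcam, not called there, reversed from -0.16 to 0.81 without day 7 replicate 1 (-0.55 to 0.81 over the fits without single libraries, the lowest without day 7 replicate 3), 0.11 without day 10 replicate 3, 0.11 without both libraries and 0.11 with limma-voom, at levels near the floor. Of 6178 values of named genes over all alternatives, 5787 stayed on their side of the threshold, 381 lost and 6 gained a call, and 4 reversed.

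Whether the replicate numbers pair the libraries is not given. After the day means were removed, same-numbered libraries correlated at -0.0694 to 0.433, 5 of 9 pairs above 0.1, and 4 of 9 libraries correlated best with their own number on both other days. With the replicate number as a block, 6319, 1374 and 8565 genes passed, 7992 among the 3 days and 1263 for the step difference, and 12, 15 and 11 lists. The block added endothelium, which fell, for day 10 against day 3 (adjusted p = 0.0312 against 0.169, and 6 against 3 of 10 genes lower), and mesothelium (0.0499 against 0.0593) and p53 and cell cycle arrest (0.0257 against 0.0754) for day 10 against day 7. Their adjusted p = 0.344, 0.344 and 0.632 with an estimated correlation and the block, where 0, 0 and 0 lists passed in the 3 comparisons. The block alone ended no list call.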

Other observations

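The tendon, bone, cartilage, Hox, Y-linked and endothelial genes of this part, and the tests on them, were chosen only after the result was seen.

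Hox genes were compared between day 3 and day 10, without a test between paralog groups. Of 17 tested genes of groups 1 to 7, 13 fell and 0 rose, such as Hoxa5, which patterns lung mesenchyme (96.7 ± 5.62 to 42.9 ± 11.8 CPM, log2 change -1.17), Hoxb5 (-1.48) and Hoxd3 (-3.62). Of 19 genes of groups 8 to 13, 17 stayed under 1 CPM in every library. Of the 3 tested, Hoxd8 rose from 0.207 to 11.8 CPM and Hoxd9 from 0 to 0.511 CPM, while Hoxb8 was not called (log2 change -0.44, adjusted p = 0.0811).

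Of genes known from tendon and bone, some rose and others fell or were not called. The tendon genes Tnmd and Kera rose from 7.88 ± 1.84 to 91.3 ± 61.6 CPM and from 10.5 ± 1.44 to 534 ± 189 CPM, while the tendon transcription factors Scx and Mkx fell by 2.73 and fell by 2.51 on the log2 scale and Thbs4 was not called (log2 change -0.16, adjusted p = 0.717). The bone genes Runx2 and Postn rose to 35.7 ± 14.5 and 1729 ± 539 CPM from 4.43 ± 1.01 and 149 ± 18.6 CPM, and Sp7 rose from 0.675 to 5.19 CPM. The cartilage genes Col2a1 and Acan stayed at or under 0.893 and 0.141 CPM in every library, and Col9a1 fell from 2.65 ± 0.995 to 0.106 ± 0.0999 CPM (log2 change -4.71, adjusted p = 0.000141).

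Libraries of 1 replicate number resembled each other in sex-linked and endothelial transcripts. Summed Y-linked genes stood at 148, 58.1 and 248 CPM in replicates 1, 2 and 3 of day 3, at 179, 51.7 and 250 CPM on day 7 and at 154, 54.3 and 273 CPM on day 10. Xist, the RNA of the inactive X chromosome, stood at 1.37, 0.312 and 0.388 CPM in replicate 3 of days 3, 7 and 10, and between 455 and 969 CPM in the other 6 libraries. Mean log2 CPM of endothelial genes was 2.58, 2.89 and 3.65 on day 3, 1.75, 2.86 and 3.40 on day 7 and 0.726, 1.69 and 2.46 on day 10. A hypothesis is that same-numbered libraries may come from one pool of embryos. Over the 36 arrangements of numbers within days, the exact p was 0.0278 for the Y-linked and 0.0278 for the endothelial genes, the smallest these arrangements can give, and 0.0278 after adjustment for 2 tests. These genes were picked because they were seen to recur, so the p restates that observation and does not bear on the hypothesis, which stays open.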
